A study of Mus musculus with 10 samples.

How the data were processed

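Spatial transcriptomics was done on 10 coronal sections of mouse forebrain with the Xenium in situ platform, which images single RNA molecules in tissue and decodes each from the colours it shows over cycles of probe hybridisation. Per the labels, brains were fixed in 4% paraformaldehyde and frozen, and sections 10 µm thick were imaged with a panel of 347 genes, of which 100 were custom. Sections fell into 3 ages, E15 (3 sections), E18 (4) and P2 (3). Per the labels, the embryos were of the outbred strain CD1 and the pups C57BL/6, and the E15 dams received 200 µL of 0.1% bovine serum albumin 48 h before collection. Per the file headers, each age had its own instrument run and the sections lay on 4 slides.

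The deposited matrices hold whole-number counts of decoded transcripts per gene and cell, with no normalization, per the file headers. The deposited counts were made by the instrument software, which kept transcripts at a decoding quality of at least 20 and assigned them to cells whose outlines were grown 2 µm from the nucleus. The fraction of transcripts past that quality and the fraction assigned to cells were taken from the deposited run summaries. Cell positions in micrometres and areas in square micrometres came from the deposited cell tables. The version of the instrument software was given as unknown in the file headers. No aligner or genome build was needed, and none is given in the sources used here. Of the 347 gene symbols, 346 were in the RefSeq gene table of the reference, which was used for names only. The 27 negative control probes, 41 negative control codewords, 125 unassigned codewords and 1 deprecated codeword stayed out of all totals and tests.

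Cells with at least 20 gene transcripts were kept, 99.2% of cells at E15, 99.2% at E18 and 99.6% at P2. From each section 6000 cells were drawn with a fixed seed, scaled to 123 transcripts, log transformed and reduced to 30 principal components. A graph of 15 nearest neighbours with shared-neighbour weights was clustered with the Leiden method at resolution 1, and the remaining cells took the cluster of most of their 15 nearest drawn cells. This gave 30 clusters. A cluster was named from markers fixed before the data were examined, when at least 3 of them stood among its 20 leading genes by fold (with 50 CPM added), the best class stood alone there, and its 10 leading genes held no more markers of another class than of its own. No doublet caller was run, since cells were outlined in tissue and an outline can take in transcripts of its neighbours.

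Of the 30 clusters 24 were named, in 12 classes. The thresholds of this naming, and 2 refusals, were set after the clusters were seen. Cluster 9 was refused a glutamatergic name because Gad1 was among its leading genes, and cluster 4 an interneuron name because Penk and Foxp2 led it. The clusters left unnamed held these mean shares of cells at E15, E18 and P2. Cluster 4 held 0.258%, 7.85% and 12.2%, cluster 8 10.7%, 4.04% and 0.521%, and cluster 9 1.74%, 4.56% and 4.29%. Cluster 15 held 3.05%, 3.21% and 0.232%, cluster 24 0%, 0.0213% and 2.31%, and cluster 29 0.101%, 0.00646% and 0.00029%. Cluster 8 was led by Eomes, Nrn1 and Neurod1 but had only 2 markers of intermediate progenitors, tied with another class. Cluster 24 had 5 radial precursor markers among its 20 leading genes but 1 against 2 of another class among its 10 leading genes, and cluster 15, with 4 of pallial neurons, likewise had 1 against 2. The panel held only 2 markers each for ependymal cells (Foxj1 and Spag16, both leading cluster 24) and intermediate progenitors. Neither name could thus be given. Names rebuilt in this way may differ from those of the study.

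The 19 genes among the 10 leading genes of either radial precursor-like cluster are not treated as results within that class. Emx1, Aldoc, Mki67, Slc1a3, Vcam1, Hat1 and Inpp4b stand among the next 10 leading genes. Dorsal and ventral cells were to be told apart by the classes of their neighbours. This vote could not be made, since no striatal projection neuron-like cell was found at E15, so all radial precursor-like cells were used, as laid down for that case. To measure the walls all the same, the roof and the lateral wall of the ventricle were drawn by hand on maps of cell positions, a choice made after seeing the data. All cells within 50 µm inside and 15 µm outside the line formed the strip, and radial precursor-like cells were taken within 100 µm. The roof lines measured 424 to 1436 µm and the lateral lines 771 to 1291 µm.

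Counts were summed per section over all cells, per class or per wall, where a section had at least 50 cells. A summed set of radial precursor-like cells held 1433113 to 2173892 transcripts at E15, 940299 to 1448963 at E18 and 91391 to 120296 at P2, and at P2 the roof sums held 9052 to 17091 and the lateral sums 10245 to 14153. Sums were scaled by TMM and filtered with filterByExpr. Ages were compared with the edgeR quasi-likelihood test in 1 fit over all sections, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The SE of a log2 fold change is its size over the root of the F statistic. Walls were compared in a fit with section as a block, where the interaction is the age change at the roof minus that at the lateral wall. Gene lists with at least 3 tested members were tested with limma camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Lists for proliferation (Mki67 and Hat1), ependymal cells (Foxj1 and Spag16) and choroid plexus (Clic6) had fewer members on the panel and were not tested as lists. In radial precursor-like cells Hat1 changed by -0.68 ± 0.11 from E15 to E18 and by -0.29 ± 0.11 from E18 to P2. Spag16 (0.37 and 0.49) did not pass at either step but rose by 0.85 ± 0.26 from E15 to P2, and Clic6 (0.70, 0.02 and 0.72) did not pass. Shares of cells with a proliferation transcript were compared by two-sided exact permutation tests, after thinning cells to 40 transcripts.

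Named genes followed a rule set before the data were examined. In radial precursor-like cells these were the 10 largest log2 fold changes each way per comparison among genes with an adjusted p under 0.05, no overlap between the sections of both ages and a mean of at least 100 CPM, and in whole sections the 5 largest each way. Between walls and for the interaction the 5 largest each way past the threshold were taken, in other classes 3 each way, and up to 4 members per list by smallest p. Egfr, Gfap, Emx1, Eomes, Gsx2, Dlx2, Mki67, Olig2, Aqp4, Foxj1, Hes5, Nes, Slc1a3, Aldoc and Tfap2c were named whatever their value, and 1 further gene of this list is not reported here. The roof strip, the roof sums and the clusters fitted alone were added after seeing the data and follow the same rule. No fold is given against a group with 3 counts or fewer.

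Each step was tested on simulated counts drawn from the means and totals of these sections. In radial precursor-like cells (340 genes) a log2 change of 1 was recovered for 95.5% of changed genes from E15 to E18, 76.1% from E18 to P2 and 76.1% from E15 to P2, and a change of 0.5 for 53.7%, 41.8% and 32.8%. For whole sections (347 genes) a change of 1 was recovered for 98.5%, 98.5% and 97.0%. For the interaction (276 genes) it was recovered for 53.7%, 23.9% and 26.9%. There both walls were drawn from the mean roof levels and so started equal, while the walls of the data differed and 310 genes were tested. Alternatives were DESeq2, library totals in place of TMM, no filter, thinning, other cell minimums, another cluster resolution, the replicate number as a block and leaving out each section. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.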

Results

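Transcripts of 347 genes were located in coronal mouse brain sections that contained the lateral ventricles, at embryonic day 15 (E15), embryonic day 18 (E18) and postnatal day 2 (P2). The stated purpose of the series was to study the dorsal ventricular-subventricular zone, the layer of dividing precursors that lines the ventricle, across this perinatal window. There were 3 sections at E15, 4 at E18 and 3 at P2. The files held 879856 cells. A section held a mean of 64641 ± 4192 cells at E15, 85913 ± 4233 at E18 and 114093 ± 15093 at P2 (SD of sections). Gene transcripts assigned to cells numbered 6956692 to 7347451 per section at E15, 11327731 to 13592889 at E18 and 14576597 to 19873261 at P2. The mean over sections of the median transcripts per cell was 101 at E15, 125.5 at E18 and 144 at P2.

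Age was not the only difference between the groups. Each age was imaged in its own instrument run, the P2 mice were C57BL/6 and the embryos CD1, and the E15 dams had received an injection of buffered saline with albumin 48 h before collection. Run cannot be told apart from age in any comparison, strain in any comparison with P2, or the injection in any comparison with E15. The share of transcripts that reached the decoding quality threshold was 69.8 ± 4.24% at E15, 92.2 ± 2.66% at E18 and 80.2 ± 0.805% at P2. The labels do not say that the sections came from separate animals, so p-values measure the spread between these sections, which may be technical.

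Cells were clustered on their transcripts, and the classes were named from markers fixed before the data were examined. Radial precursor-like cells, the class named for the neural stem cells of the embryonic ventricular wall, formed 2 clusters. Cluster 3, called pallial-type here, was led by Tfap2c, Eomes, Veph1 and Gli3. Cluster 10, called subpallial-type, was led by Gsx2, and its leading 10 genes held as many markers of the subpallial progenitor class, and of the astrocyte class (Acsbg1 and Slc39a12), as of its own. The pallial-type cluster held 73.6 ± 6.75% of the radial precursor-like cells of a section at E15, 56.0 ± 2.84% at E18 and 34.3 ± 2.01% at P2. It thus held most of the class at E15 and E18, and the subpallial-type cluster held most at P2. A section had 14103 to 17154 radial precursor-like cells at E15, 5652 to 8588 at E18 and 665 to 1018 at P2. Shares of cells per class were not compared, because the markers of each class that could be fitted differed between ages.

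**Figure D1:**
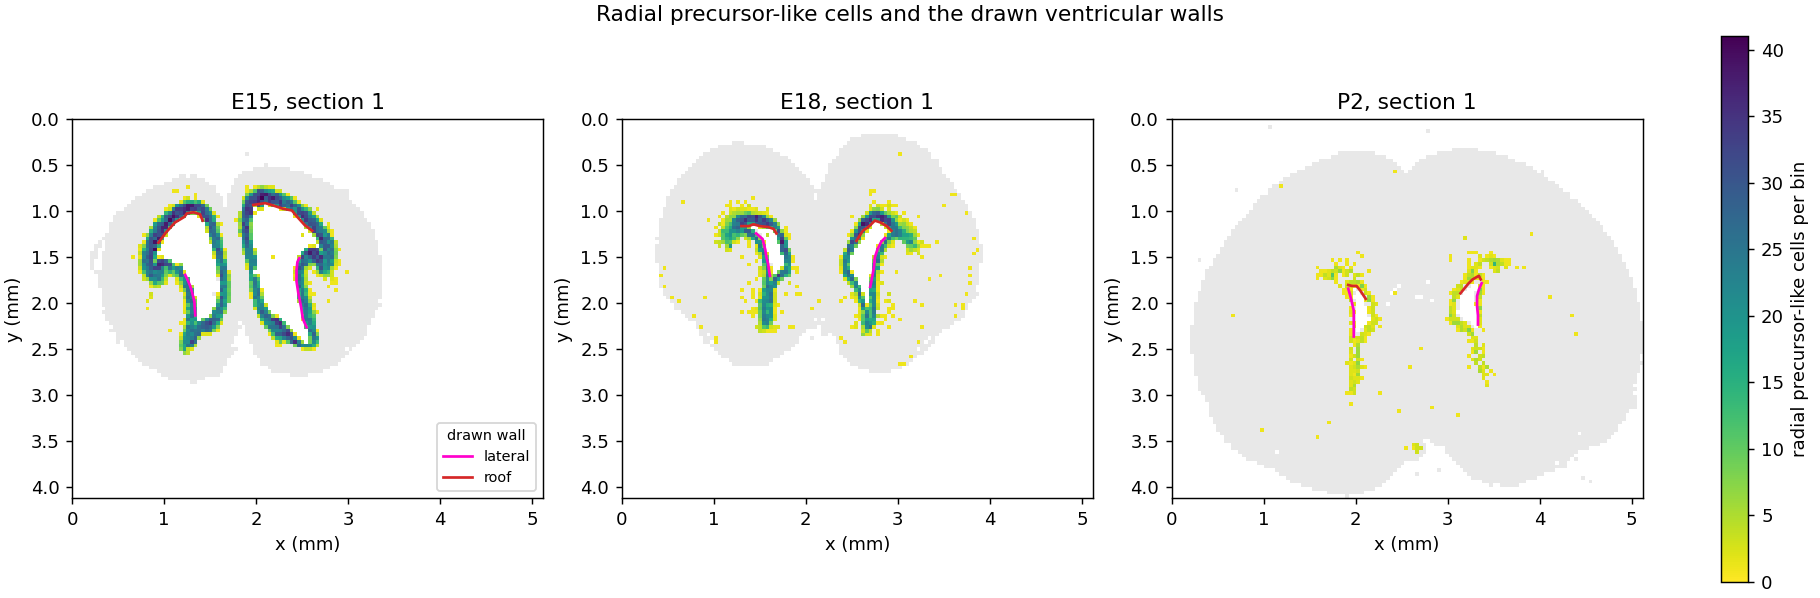
Position of radial precursor-like cells in section 1 of each age, as cells per bin of 40 µm (colour), with all other tissue in grey, both axes in millimetres and the drawn roof and lateral walls of the ventricle as lines. Section 1 held 16035 of these cells at E15, 7681 at E18 and 814 at P2. Within 50 µm of the drawn roof the pallial-type cluster held a mean of 97.9%, 95.4% and 7.26% of all cells at these ages. Within 50 µm of the lateral wall the subpallial-type cluster held 92.2%, 83.9% and 7.98%.

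Whole sections were compared first, to show how the tissue as a whole differed between ages. From E15 to E18 the receptor gene Egfr rose by a log2 fold change of 1.73 ± 0.14 (SE, n = 3 and 4 sections; adjusted p = 4.4e-06), and Gfap, the intermediate filament of astrocytes and postnatal stem cells, rose by 2.12 ± 0.18. Rspo2, a secreted activator of Wnt signalling, rose by 2.77 ± 0.25, Rasgrf2, a Ras exchange factor, by 2.32 ± 0.20, Gucy1a1, a guanylate cyclase subunit, by 2.01 ± 0.19, and the extracellular matrix gene Fmod by 2.002 ± 0.14. Olig1, an oligodendrocyte lineage factor, rose by 1.88 ± 0.24. The neuropeptide gene Vip changed by -2.74 ± 0.56, the neurite growth gene Nrn1 by -2.30 ± 0.15, and the pallial genes Tfap2c by -2.23 ± 0.25, Eomes by -1.98 ± 0.31, Gli3 by -1.88 ± 0.16 and Emx1 by -1.81 ± 0.21. Nes, the filament gene of neural precursors, changed by -1.02 ± 0.12 and the proliferation gene Mki67 by -0.90 ± 0.25 (adjusted p = 0.0093).

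Between E18 and P2, Lamp5 rose by 5.08 ± 0.32 (adjusted p = 2e-07), Gfap by 4.17 ± 0.17 (adjusted p = 7.8e-09), the striatal neuropeptide genes Pdyn by 3.24 ± 0.33 and Penk by 3.15 ± 0.42, and the astrocyte water channel gene Aqp4 by 3.18 ± 0.26. Eomes changed by -3.86 ± 0.36, Tfap2c by -2.999 ± 0.27, Neurod1 by -2.41 ± 0.15 and Nrn1 by -2.23 ± 0.16. Sp8 changed by -2.09 ± 0.25, Gsx2 by -1.62 ± 0.16 and Dlx2 by -1.51 ± 0.23. Mki67 changed by -1.64 ± 0.27 and Nes by -1.39 ± 0.12, while Egfr did not pass the test (0.30 ± 0.13, adjusted p = 0.057). Between E15 and P2, Gfap rose by 6.29 ± 0.22, Cplx3, a synaptic complexin gene, by 4.62 ± 0.16 and Strip2 by 4.36 ± 0.35, and Ebf3, a transcription factor of Cajal-Retzius neurons, changed by -3.72 ± 0.13. The E18 values of Gfap and Ebf3 each included 1 section far from the other 3.

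Of the 347 genes, 118 rose and 101 fell from E15 to E18, 123 rose and 130 fell from E18 to P2, and 133 rose and 138 fell from E15 to P2 (edgeR quasi-likelihood test, Benjamini-Hochberg). A change of at least 2-fold was called for 79, 105 and 161 genes. The sections of the 2 ages did not overlap for 206, 264 and 281 genes, where chance gives 5.71% of genes with 3 against 4 sections and 10% with 3 against 3. Without TMM the median gene shifted by 0.21, 0.36 and 0.57 (log2), and the share of calls that were higher moved from 53.9 to 65.9%, from 48.6 to 69.3% and from 49.1 to 71.3%. Slc1a3, a glial glutamate transporter gene, changed by -0.32 ± 0.11 from E15 to P2 with TMM and by 0.26 without it.

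Radial precursor-like cells were compared next, to follow the gene expression of the precursors themselves. All of these cells of a section were summed, because the planned split into dorsal and ventral cells could not be made. Clusters outside the class also had its markers, namely cluster 24 (99.1% of its cells from P2) and the astrocyte-like cluster 13 (85.5%). At resolution 2 the class held 1674, 1797 and 1551 cells in the P2 sections, in place of 814, 1018 and 665. A change toward P2 may thus come in part from which cells kept the class, which was not tested. The genes that rose most from E15 to E18 included Vnn1, which encodes a pantetheinase, by 3.64 ± 0.24 (adjusted p = 2.6e-07), Gfap by 3.33 ± 0.26 (adjusted p = 5.1e-07) and Egfr by 2.46 ± 0.20 (adjusted p = 7.1e-07). Egfr stood at 833 ± 307 CPM (counts scaled to a fixed section total with TMM factors) at E15, 4591 ± 184 at E18 and 12633 ± 1173 at P2 (SD, n = 3, 4 and 3 sections). The matrix genes Hapln1 and Adamts2 rose by 2.60 ± 0.20 and 2.55 ± 0.24, the galectin gene Lgals3 by 2.61 ± 0.32, Olig1 by 2.49 ± 0.26, Crh, a neuropeptide gene, by 2.33 ± 0.50 and the glutamate receptor auxiliary gene Gsg1l by 2.13 ± 0.24. Aqp4 rose by 2.05 ± 0.20, the glycolytic gene Aldoc by 1.29 ± 0.19, the cilium regulator Foxj1 by 0.83 ± 0.16, Slc1a3 by 0.70 ± 0.11 and Olig2 by 0.59 ± 0.19.

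The genes that fell from E15 to E18 included Emx1, a homeobox factor of the dorsal telencephalon (-2.12 ± 0.15, adjusted p = 2.6e-07), Chodl (-2.35 ± 0.22), Vip (-2.30 ± 0.42), Ebf3 (-1.91 ± 0.19), Nrn1 (-1.84 ± 0.23), the long non-coding RNA Rmst (-1.84 ± 0.21), Eya4 (-1.81 ± 0.21), Ikzf1 (-1.52 ± 0.16), Rprm (-1.43 ± 0.16) and Rnf152 (-1.39 ± 0.15). Nes fell by 0.39 (SE 0.11, adjusted p = 0.011). Mki67 (-0.41 ± 0.19, adjusted p = 0.078) and Dlx2 (0.10 ± 0.23, adjusted p = 0.73) did not pass. Some of these changes differed between the clusters. In the subpallial-type cluster alone Rmst rose by 1.11 (adjusted p = 0.0016) and Dlx2 fell by 0.70, and in the pallial-type cluster alone Emx1 fell by 1.64 (SE 0.12) and Rmst fell by 2.0025 (SE 0.22). Some of the named genes had a like change elsewhere. The median over the other classes in which a gene was measured had the same direction and at least 0.5 times the size for Egfr (1.96), Gfap (2.36), Aqp4 (1.99), Vnn1 (1.90), Olig1 (1.78), Adamts2 (1.33), Olig2 (1.17), Vip (-3.09), Nrn1 (-1.80), Ebf3 (-1.27), Emx1 (-1.14) and Nes (-0.37).

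**Figure D2:**
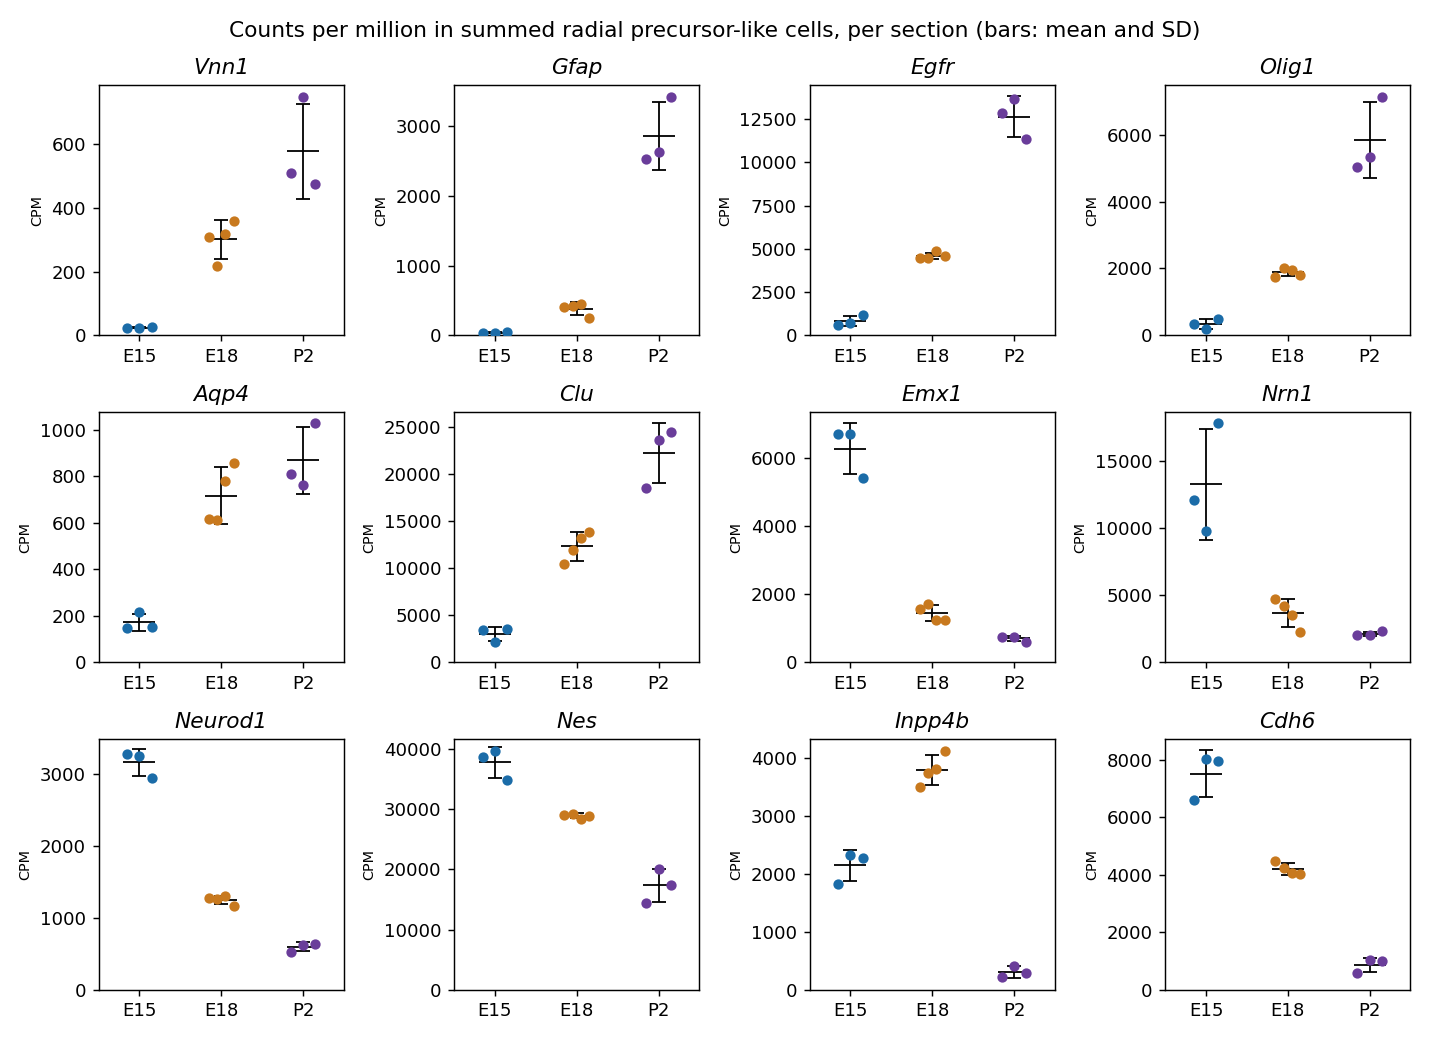
CPM of 12 genes in the summed radial precursor-like cells of each section, with 1 point per section and bars for the mean and SD of the 3 E15, 4 E18 and 3 P2 sections. Egfr rose from a mean of 833 at E15 to 4591 at E18 and 12633 at P2, and Emx1 went from 6263 to 1442 and 704.

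The radial precursor-like cells gained, from E18 to P2, Egfr by 1.46 ± 0.18 (adjusted p = 1.9e-05), Olig2 by 0.87 ± 0.19 (adjusted p = 0.0013), Gfap by 2.90 ± 0.22 and Pdgfra, a growth factor receptor gene of oligodendrocyte precursors, by 1.90 ± 0.19. Other genes that rose were the copine genes Cpne4 (3.83 ± 0.30) and Cpne8 (2.503 ± 0.20), the actin regulator Fam107a (3.29 ± 0.27), the Rac exchange factor Prex2 (3.21 ± 0.21), Necab1 (2.34 ± 0.28), the osteopontin gene Spp1 (2.26 ± 0.51), the syntrophin gene Sntb1 (2.14 ± 0.20) and the vesicle gene Rab3b (2.003 ± 0.18). The phosphoinositide phosphatase gene Inpp4b changed by -3.64 ± 0.20 (adjusted p = 1.3e-08), the laminin gene Lama1 by -2.30 ± 0.32, the cadherin gene Cdh6 by -2.28 ± 0.18, Ebf3 by -2.02 ± 0.30, the neuropeptide gene Cort by -2.02 ± 0.20, the ubiquitin ligase gene Pdzrn3 by -1.97 ± 0.18 and the transcription factor Pou3f1 by -1.97 ± 0.23. Emx1 changed by -1.03 ± 0.17, Aldoc by -0.99 ± 0.19, Nes by -0.74 ± 0.12 and Slc1a3 by -0.30 ± 0.11. Aqp4 (0.27 ± 0.19, adjusted p = 0.26), Dlx2 (0.27 ± 0.23, adjusted p = 0.34) and Mki67 (-0.17 ± 0.19, adjusted p = 0.47) did not pass. In the subpallial-type cluster alone Pou3f1 (0.53, adjusted p = 0.30) and Emx1 (0.38, adjusted p = 0.32) did not fall. Foxj1 rose by 0.51 ± 0.16 in the whole class and fell by 0.40 (SE 0.14) in the pallial-type cluster alone.

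The P2 cells were few and lay among cells of other classes. Of the 100 genes higher at P2 than at E18, 12 stood above the level of the other cells within 30 µm in all 3 P2 sections, and 74 stood below it in all 3. Egfr was among the 12, with a mean of 14096 CPM of the section totals without TMM in radial precursor-like cells and 4808 CPM in those neighbours, as were Olig2 (12193 and 7055 CPM), Jag1 and Sntb1. Gfap (3176 and 4345 CPM), Cpne4, Fam107a, Prex2 and Pdgfra were lower than in the neighbours. Gfap rose from E18 to P2 in each of the 8 other classes fitted, by 4.48 to 7.05, and Aqp4 by 3.80 to 4.62. With only the cells of which at least 50% of the 10 nearest cells were of the same class, 1 P2 section with 59 such cells was left, assumed to vary like the other groups, and 44 genes passed in place of 201. On so few cells of 1 section single genes were not sorted by this fit.

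Across the whole interval, from E15 to P2, Gfap rose by 6.23 ± 0.29, the receptor gene Gpr17 of oligodendrocyte precursors by 4.92 ± 0.36, Vnn1 by 4.59 ± 0.27, Cpne4 by 4.51 ± 0.34, Fam107a by 4.14 ± 0.30, Olig1 by 4.12 ± 0.29, Egfr by 3.92 ± 0.22, Gsg1l by 3.61 ± 0.27, Hapln1 by 3.48 ± 0.23 and Cpne8 by 3.41 ± 0.23. Ebf3 changed by -3.93 ± 0.30, Lama1 by -3.47 ± 0.32, Emx1 by -3.15 ± 0.18, Cdh6 by -3.12 ± 0.19, the axon guidance gene Sema3a by -2.93 ± 0.23, Cort by -2.92 ± 0.20, Inpp4b by -2.82 ± 0.21, Nrn1 by -2.64 ± 0.27 and Plcxd2 by -2.63 ± 0.15. Nes changed by -1.12 ± 0.12 and Mki67 by -0.59 ± 0.21 (adjusted p = 0.023). Emx1 did not pass in the subpallial-type cluster alone (0.25, adjusted p = 0.54). In these cells 1 E18 section stood far from the other 3 for Gfap and Fam107a.

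Of 340 genes tested in radial precursor-like cells, 105 rose and 89 fell from E15 to E18, 100 rose and 101 fell from E18 to P2, and 106 rose and 106 fell from E15 to P2 (edgeR quasi-likelihood test, Benjamini-Hochberg). The P2 sums held far fewer transcripts, and with all sums thinned to the smallest one the counts were 63 and 57, 77 and 72, and 93 and 82 of 261. Without the 19 genes that lead the 2 clusters the counts were 100 and 83, 100 and 86, and 104 and 95 of 321. Sections of the 2 ages did not overlap for 194, 205 and 217 genes, against the same chance shares as above. The share of calls that were higher moved from 54.1 to 63.0%, from 49.8 to 60.9% and from 50 to 62.7% without TMM, with the median gene shifted by 0.15, 0.16 and 0.31. Of the 201 genes called from E18 to P2, 25 changed further in their own direction than in each of the 8 other classes, a test devised after the results were seen. They included Inpp4b, Cdh6, Pou3f1, Aldoc, Cpne4, Pdgfra and the astrocyte receptor gene Ntsr2. Acsbg1, Hes1 and Mt3, which lead a cluster, were also among them. Of the 11 higher genes among the 25, 9 stood below the level of the other cells within 30 µm in all 3 P2 sections, Cpne4 and Pdgfra among them. Such genes numbered 7 from E15 to E18, among them Adamts2, Gsg1l and the fibronectin gene Fn1.

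Gene lists fixed before the data were examined were then followed in these cells. Members are given as rose, fell and not passed among those on the panel, for E18 against E15, P2 against E18 and P2 against E15 in that order. All 3 members of the dorsal patterning list fell in each comparison, namely Emx1, Tfap2c and Gli3, of which the last 2 lead the pallial-type cluster (camera adjusted p = 0.0754, 0.120 and 0.0754). All 3 also fell in the pallial-type cluster alone, and 2, 1 and 2 of them in the subpallial-type cluster alone. In the pallial neurogenic list 3 of 4 members fell in each comparison (adjusted p = 0.172, 0.120 and 0.120), among them Eomes, which leads a cluster, with Neurod1, a factor of newborn neurons, at -1.34 ± 0.12 and -1.07 ± 0.14. Counts within clusters differed, with 1, 3 and 3 of the 4 fallen in the pallial-type cluster alone, 2, 0 and 2 in the subpallial-type cluster alone and 0, 3 and 3 in radial precursor-like cells at the drawn roof. The embryonic radial precursor list had 3 of 5 members fall in each comparison (adjusted p = 0.195, 0.236 and 0.172), of which only Nes leads neither cluster.

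Among glial lists, 5, 2 and 4 of 8 astrocyte genes rose and 0, 3 and 0 fell (adjusted p = 0.0754, 0.913 and 0.120), with Gfap and Aqp4 as given above. Acsbg1 and Slc39a12, which lead the subpallial-type cluster, are among the 5 that rose and the 3 that fell. Of 10 quiescent or adult stem cell genes, 6, 3 and 3 rose and 3, 5 and 2 fell (adjusted p = 0.244, 0.561 and 0.688), with Mt3, which leads a cluster, among the 6 and the 5. Within it Vnn1 and the chaperone gene Clu rose at both steps, Clu by 2.01 ± 0.18 and 0.85 ± 0.17, and Id2, an inhibitor of differentiation factors, changed by -0.78 ± 0.17 and -0.54 ± 0.17. Of 9 oligodendrocyte lineage genes, 6, 7 and 6 rose and 2, 2 and 2 fell (adjusted p = 0.478, 0.0973 and 0.120), led by Olig1, Pdgfra and Gpr17, and Zfp536 fell at both steps. In the subpallial-type cluster alone 1, 5 and 5 of 8 rose and 1, 2 and 2 fell. The growth factor list of 10 genes had 6, 5 and 5 rise and 1, 4 and 3 fall (adjusted p = 0.244, 0.509 and 0.330). In it Egfr rose at both steps, as did Igf1 by 1.43 ± 0.20 and 1.24 ± 0.21, and Igf1r, the receptor gene of its product, changed by -0.33 ± 0.11 and -0.39 ± 0.11.

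Of 8 genes of the subpallial and olfactory interneuron lineage, 4, 5 and 5 rose and 1, 0 and 0 fell (adjusted p = 0.307, 0.120 and 0.120), with Dlx1 at 0.73 ± 0.17 and 0.55 ± 0.16 and Dlx5 at 1.25 ± 0.21 from E18 to P2. These counts differed between the clusters. In the pallial-type cluster alone 2, 8 and 7 of the 8 rose and 1, 0 and 0 fell, and in the subpallial-type cluster alone 1, 2 and 1 rose and 2, 0 and 2 fell. Of 6 ventral patterning genes, 4, 3 and 4 rose and none fell in the summed class (adjusted p = 0.236, 0.238 and 0.120). In the pallial-type cluster alone 1, 5 and 6 of them rose and none fell, and in the subpallial-type cluster alone 1, 2 and 2 rose and 2, 0 and 2 fell. Both lists hold genes that lead that cluster. Of 5 Notch pathway genes, 0, 1 and 1 rose and 1, 3 and 4 fell (adjusted p = 0.509, 0.447 and 0.359). There the ligand gene Jag1 rose by 1.04 ± 0.16 from E18 to P2, while Hes1, Hes5 and Notch1, which lead a cluster, made up the 3 that fell. Of 5 immediate early and stress genes, 2, 0 and 1 rose and 2, 1 and 2 fell (adjusted p = 0.851, 0.625 and 0.654).

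Markers of other cell types moved in both directions. Of 17 pallial neuron genes 3, 5 and 4 rose and 7, 6 and 6 fell (adjusted p = 0.315, 0.688 and 0.654). Of 5 striatal genes 2, 4 and 3 rose and 2, 0 and 1 fell (adjusted p = 0.927, 0.172 and 0.463), and Penk rose by 1.95 ± 0.46 from E18 to P2. Of 12 interneuron genes 4, 5 and 6 rose and 3, 3 and 3 fell (adjusted p = 0.882, 0.667 and 0.688), and Gad1, an enzyme of GABA synthesis, rose by 1.63 ± 0.20 from E18 to P2 while standing below its level in the neighbours. Of 12 microglia genes 4, 6 and 6 rose and 2, 2 and 1 fell (adjusted p = 0.654, 0.385 and 0.385). Of 17 endothelial genes 1, 1 and 2 rose and 2, 2 and 3 fell (adjusted p = 0.834, 0.689 and 0.688), and of 22 mural and meningeal genes 6, 6 and 7 rose and 4, 9 and 6 fell (adjusted p = 0.654, 0.645 and 0.913).

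Counts adjusted over the list alone were equal except for 4 lists. The growth factor list had 6 and 4 from E15 to P2, and the interneuron list 6 and 4 there. The endothelial list had 1 and 1, 0 and 0, and 0 and 1, and the mural and meningeal list 4 and 3 from E15 to E18. With camera, which compares a list with the other genes, 0 of 51 tests passed after adjustment (smallest adjusted p = 0.0754), 13 had an unadjusted p under 0.05, and without TMM 2 passed. With an estimated correlation 0 passed (smallest adjusted p = 0.743) and 1 had an unadjusted p under 0.05. The test fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, passed for 34. The camera direction was down while the median and mean change were positive for the stress list (0.10 and 0.03) and the striatal list (0.22 and 0.20) from E15 to E18 and for the mural and meningeal list (0.07 and 0.07) from E15 to P2. For the endothelial list from E15 to E18 it was down with a median of -0.04 and a mean of 0.00.

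Proliferation was followed through Mki67, a marker of cycling cells, and Hat1, a histone acetyltransferase gene of dividing cells, the 2 proliferation genes on the panel. Mki67 is among the 20 leading genes of the pallial-type cluster and Hat1 of the subpallial-type cluster, so cells may enter the class partly through them. In the summed class Mki67 passed at neither step, and the share below was not split by gene. After each cell was thinned to 40 transcripts, 80.8 ± 1.44% of radial precursor-like cells had a transcript of either gene at E15, 66.2 ± 4.18% at E18 and 63.9 ± 4.04% at P2 (SD, n = 3, 4 and 3). The difference was -14.7 points from E15 to E18 (two-sided exact permutation test, p = 0.0286, the smallest that 35 assignments allow; adjusted p = 0.0857 over 3 comparisons). It was -2.24 points from E18 to P2 (exact p = 0.486, adjusted 0.486) and -16.9 points from E15 to P2 (exact p = 0.1, the smallest possible; adjusted 0.15). In pallial glutamatergic neuron-like cells, taken as background, the share was 11.1%, 9.39% and 7.04%. Unthinned shares were 94.7%, 90.5% and 84.7% in precursors and 26.4%, 28.3% and 27.9% in neurons, at median depths of 93 to 115, 137 to 153 and 110 to 134 transcripts per cell in precursors and 97 to 109, 128 to 148 and 181 to 195 in neurons. Cells with fewer than 40 transcripts were left out, 1943 at E15, 394 at E18 and 79 at P2.

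**Figure D3:**
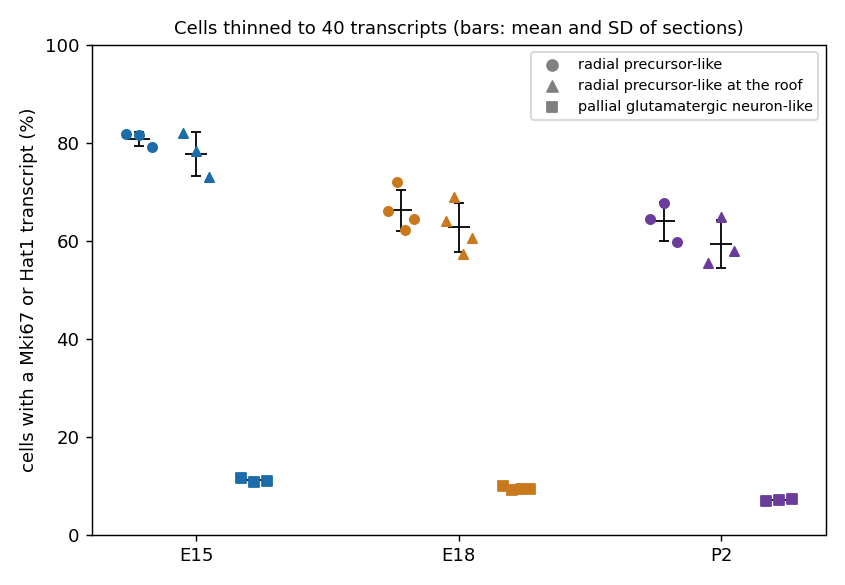
Percent of cells with an Mki67 or Hat1 transcript after thinning to 40 transcripts, 1 point per section with bars for the mean and SD, for all radial precursor-like cells, those at the drawn roof and pallial glutamatergic neuron-like cells at each age. The radial precursor-like means are 80.8% at E15, 66.2% at E18 and 63.9% at P2, and the neuron-like means lie between 7.04% and 11.1%.

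The dorsal wall itself was examined in a strip along the roof of the ventricle, drawn by hand on the images of cell positions after the data were seen. The strip reached 50 µm into the tissue, took in all cells whatever their class, and held 491 to 1670 cells per section. From E15 to E18, Olig1 rose by 4.36 ± 0.39, Gfap by 3.71 ± 0.40, Adamts2 by 3.71 ± 0.34, Egfr by 3.34 ± 0.25 (adjusted p = 1.2e-06), Aqp4 by 3.28 ± 0.30 and Dkk3, a secreted Wnt modulator, by 2.96 ± 0.22. The semaphorin gene Sema3e changed by -2.70 ± 0.25, Chodl by -2.41 ± 0.44, Eya4 by -2.05 ± 0.29, Rprm by -1.95 ± 0.18, Emx1 by -1.71 ± 0.16, Nes by -0.62 ± 0.12 and Mki67 by -0.60 ± 0.17. Eomes (-0.32 ± 0.31) and Dlx2 (0.04 ± 0.33) did not pass.

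The roof strip gained, from E18 to P2, the interneuron lineage factors Sp9 (5.08 ± 0.47), Dlx2 (4.502 ± 0.31, adjusted p = 2.3e-07), Gsx2 (4.30 ± 0.50) and Dlx5 (4.27 ± 0.32), together with Gpr17 (4.74 ± 0.44), Fam107a (4.602 ± 0.39), Gfap (4.18 ± 0.26), Foxj1 (2.40 ± 0.18, adjusted p = 2.5e-07) and Aqp4 (2.30 ± 0.22). Egfr rose by 0.83 ± 0.20 (adjusted p = 0.0032). Eomes changed by -2.34 ± 0.34, Mki67 by -2.09 ± 0.18, the Notch effector genes Hes1 and Hes5 by -2.39 ± 0.18 and -1.17 ± 0.18, Tfap2c by -1.77 ± 0.13, Nes by -0.86 ± 0.12 and Emx1 by -0.74 ± 0.17. The cells that made up the strip also changed. The pallial-type cluster held 97.9 ± 1.15% of roof strip cells at E15, 95.4 ± 0.913% at E18 and 7.26 ± 1.64% at P2. At P2 52.3 ± 4.45% belonged to cluster 24, led by Foxj1, Fam107a and Spag16, and 23.1 ± 3.19% to cluster 0, led by Sp8, Dlx2 and Sp9. Of 283 genes, 60 rose and 60 fell, 93 rose and 69 fell, and 109 rose and 87 fell in the 3 comparisons. Without TMM the median gene shifted by 0.24, 0.13 and 0.37, and the share of calls that were higher moved from 50 to 66.7% from E15 to E18 and from 55.6 to 66.0% from E15 to P2.

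Within 100 µm of the same roof, radial precursor-like cells were fitted alone. They numbered 2695 to 3358 per section at E15, 1014 to 2351 at E18 and 65 to 101 at P2. From E15 to E18, Vnn1 rose by 5.20 ± 0.54, Olig1 by 4.45 ± 0.44, Gfap by 3.80 ± 0.41 and Egfr by 3.55 ± 0.27 (adjusted p = 3.3e-08), and Sema3e changed by -2.76 ± 0.22 and Emx1 by -1.71 ± 0.14. Later, from E18 to P2, Egfr rose by 2.24 ± 0.23 (adjusted p = 6.3e-07), Dlx2 by 3.15 ± 0.29, Dlx1 by 2.94 ± 0.29, Olig2 by 1.29 ± 0.20 and Foxj1 by 1.04 ± 0.19, and Pou3f1 changed by -3.25 ± 0.35, Inpp4b by -2.92 ± 0.29 and Emx1 by -0.80 ± 0.18. The mix of clusters changed at this step, since the subpallial-type cluster held 0.147 ± 0.0755% of these roof cells at E15, 0.968 ± 0.293% at E18 and 26.1 ± 3.23% at P2. In the pallial-type cells of the roof alone, with 2 P2 sections of at least 50 such cells, Egfr rose by 2.53 ± 0.23 (adjusted p = 3.5e-06), Dlx2 by 2.88 ± 0.35, Dlx1 by 3.06 ± 0.31 and Olig2 by 1.46 ± 0.22 from E18 to P2, while Foxj1 did not pass (0.04 ± 0.29, adjusted p = 0.95). Of 300 genes, 80 rose and 74 fell, 62 rose and 59 fell, and 84 rose and 81 fell. The share of calls that were higher moved from 52.0 to 68.1%, from 51.2 to 62.2% and from 50.9 to 63.6% without TMM.

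At the lateral wall, drawn the same way and next to the future striatum, radial precursor-like cells numbered 1341 to 1605 at E15, 828 to 1054 at E18 and 71 to 93 at P2. There Vnn1 rose from E15 to E18 by 2.91 ± 0.47, Lgals3 by 2.86 ± 0.25, Aqp4 by 2.20 ± 0.26, Rmst by 2.18 ± 0.32 and Egfr by 1.61 ± 0.29, while Id2 changed by -1.61 ± 0.23, Dlx2 by -0.65 ± 0.17 and Nes by -0.41 ± 0.10. Later, from E18 to P2, Fam107a rose by 4.63 ± 0.39, Prex2 by 3.45 ± 0.34, Gfap by 3.04 ± 0.44, Egfr by 1.09 ± 0.29 and Foxj1 by 1.08 ± 0.21. Inpp4b changed by -5.61 ± 0.45 on 4 transcripts at P2, Sema3a by -2.94 ± 0.40, Cdh6 by -2.81 ± 0.22 and Nes by -0.86 ± 0.10. Of 275 genes, 40 rose and 31 fell, 45 rose and 53 fell, and 63 rose and 66 fell. When single sections were left out, the count of 71 from E15 to E18 ranged from 47 to 94 and its 40 higher genes from 23 to 48, both moved by over 1.5 times by E15 section 1. The 45 higher genes from E18 to P2 ranged from 25 to 52, with P2 sections 1 and 2 moving them that far.

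Roof and lateral wall were then compared within sections, with section as a block. The walls also differed in cluster. At E15, E18 and P2 the pallial-type cluster held 99.9%, 99.0% and 73.9% of the radial precursor-like cells at the roof. The subpallial-type cluster held 94.6%, 99.3% and 98.4% of those at the lateral wall. At E15 the roof exceeded the lateral wall in Emx1 by 6.08 ± 0.25 (adjusted p = 3.5e-13), Pou3f1 by 4.70 ± 0.33, Nrn1 by 4.69 ± 0.29 and Fezf2, a factor of cortical neurons, by 4.22 ± 0.33. The lateral wall exceeded the roof in Dlx2 (-6.56 ± 0.24, adjusted p = 1.6e-13), Dlx1 (-6.08 ± 0.26), Egfr (-2.94 ± 0.26), Olig2 (-2.17 ± 0.25) and Foxj1 (-1.37 ± 0.18). At E18 the difference was 6.00 ± 0.24 for Emx1, 2.55 ± 0.24 for Gfap, -5.68 ± 0.20 for Dlx2, -1.40 ± 0.15 for Foxj1 and -1.05 ± 0.19 for Egfr. At P2 it was 3.002 ± 0.30 for Gfap, -4.18 ± 0.58 for Fam107a (on 5 roof transcripts, all in P2 section 1), -2.65 ± 0.21 for Dlx2, -1.48 ± 0.21 for Foxj1 and -0.71 ± 0.15 for Mki67, and Egfr did not pass (0.02, adjusted p = 0.98). Of 310 genes 72 were higher at the roof and 73 lower at E15, 69 and 81 at E18 and 28 and 35 at P2. Without TMM the P2 counts were 43 and 23, so that the share of calls that were higher moved from 44.4 to 65.2%. When single sections were left out the 35 lower genes at P2 ranged from 12, without P2 section 2, to 34, with 23 without E18 section 2, and the 28 higher genes ranged from 20 to 43, highest without E15 section 2. The 63 genes in all at P2 became 39 without P2 section 2, and the 81 lower genes at E18 became 53 without E18 section 2. Without the 19 leading genes 130, 134 and 53 passed.

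**Figure D4:**
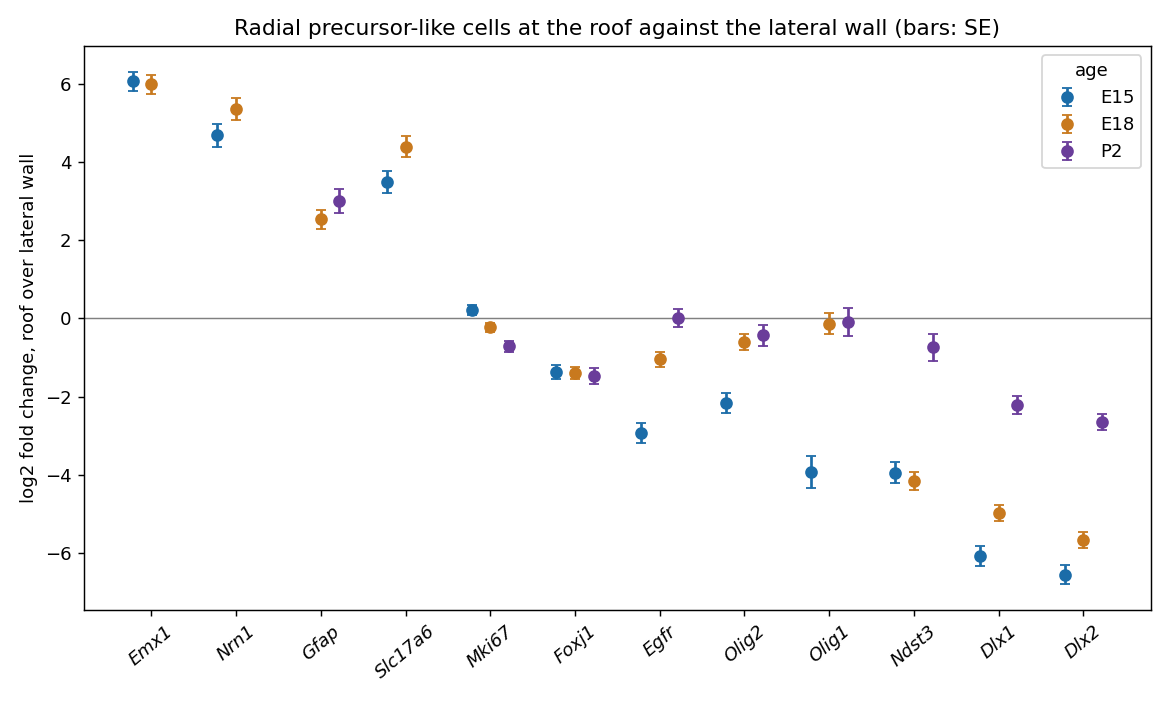
Log2 fold change of radial precursor-like cells at the roof over those at the lateral wall for 12 genes at each age, with bars for the SE of the fit over 3 E15, 4 E18 and 3 P2 sections and no point where a wall had 3 counts or fewer. Egfr goes from -2.94 at E15 to -1.05 at E18 and 0.02 at P2, and Dlx2 from -6.56 to -5.68 and -2.65.

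The age change itself differed between the walls for 41 genes from E15 to E18, 30 from E18 to P2 and 66 from E15 to P2. The share of these calls toward the roof moved from 51.5 to 67.7% without TMM from E15 to P2. Egfr rose more at the roof, by 1.89 ± 0.31 from E15 to E18 (adjusted p = 0.00043), 1.07 ± 0.30 from E18 to P2 (adjusted p = 0.028) and 2.96 ± 0.35 over both (adjusted p = 6.3e-06). Olig1 (3.80 ± 0.49) and Olig2 (1.56 ± 0.32) also differed toward the roof from E15 to E18, and Rmst (-3.29 ± 0.35) and Sema3e (-1.94 ± 0.30) toward the lateral wall. From E18 to P2 the difference was 3.02 ± 0.27 for Dlx2, 2.88 ± 0.38 for Sp9, -3.74 ± 1.10 for Pou3f1, on 9 roof and 5 lateral transcripts at P2, and -3.49 ± 0.76 for Fam107a, on the same 5 roof transcripts. At P2 roof precursor-like cells had less Dlx2 (6783 CPM) and Sp9 (2559 CPM) than the other cells within 30 µm (14493 and 7030 CPM), and more Egfr (11353 and 3951 CPM). When single sections were left out, the count of 41 from E15 to E18 ranged from 27, without E18 section 3, to 59. Its 16 genes toward the lateral wall ranged from 10 to 32, moved by over 1.5 times by E15 sections 2 and 3, E18 sections 2 and 3 and P2 section 3. The count of 30 from E18 to P2 ranged from 13 to 41 and was lowest when a P2 section was missing, its 20 genes toward the roof ranged from 9 to 22, and its 10 genes toward the lateral wall ranged from 3 to 19. The 32 genes toward the lateral wall from E15 to P2 became 19 without P2 section 1.

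The other classes of the same sections were each fitted alone, to set the precursors beside other cells. In pallial glutamatergic neuron-like cells, whose largest cluster was number 2 at E15, number 5 at E18 and number 11 at P2, 124 genes rose and 101 fell from E15 to E18 and 140 rose and 124 fell from E18 to P2, of 346. Nwd2 rose by 3.14 ± 0.14, Rasgrf2 by 3.08 ± 0.15 and Ccn2 by 2.99 ± 0.24 at the earlier step, and Cplx3 by 4.83 ± 0.19 at the later one, when Eomes changed by -3.36 ± 0.24 and Sox11, a factor of immature neurons, by -1.79 ± 0.14. In interneuron-like cells Prox1, a factor of interneurons from the caudal eminence, rose by 2.98 ± 0.15 from E15 to E18, and 133 genes rose and 123 fell from E18 to P2, of 339. In subpallial progenitor and immature interneuron-like cells Egfr rose by 2.52 ± 0.23 and Clu by 2.09 ± 0.20 from E15 to E18. In oligodendrocyte lineage-like cells the myelinating cell genes Enpp6 and Mag rose by 5.27 ± 0.24 and 4.93 ± 0.42 from E18 to P2. In endothelial-like cells Ly6a rose by 2.54 ± 0.34 from E15 to E18, and in meningeal fibroblast-like cells Spp1 rose by 5.50 ± 0.79 and, from E18 to P2, the angiotensinogen gene Agt by 4.34 ± 0.33. In Cajal-Retzius-like cells Angpt1 rose by 3.67 ± 0.28 from E15 to E18, and Nes changed by -2.89 ± 0.15 from E18 to P2.

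Genes called from E15 to E18, E18 to P2 and E15 to P2 numbered 225, 264 and 262 in pallial neuron-like cells, 164, 256 and 258 of 339 in interneuron-like cells, and 145, 212 and 207 of 335 in subpallial progenitor-like cells. They numbered 157, 145 and 193 in Cajal-Retzius-like, 84, 189 and 173 of 300 in oligodendrocyte lineage-like, 109, 155 and 192 of 313 in microglia-like, 151, 202 and 232 of 342 in endothelial-like and 156, 158 and 206 of 315 in meningeal fibroblast-like cells. Without TMM the share of calls that were higher from E18 to P2 moved from 53.0 to 68.6%, 52.0 to 71.2%, 55.2 to 79.0%, 40 to 67.7%, 47.1 to 70.7%, 51.6 to 70.8%, 53.5 to 66.7% and 49.4 to 82.2% in the same order of classes. From E15 to E18 it moved by over 10 points in pallial neuron-like (55.1 to 75.6%), interneuron-like (50 to 68.0%), Cajal-Retzius-like (58.0 to 47.2%) and meningeal fibroblast-like cells (54.5 to 28.7%). From E15 to P2 it moved to 73.5, 70.9, 72.8, 67.0 and 66.8% in pallial neuron-like, interneuron-like, subpallial progenitor-like, oligodendrocyte lineage-like and microglia-like cells, from 55.7, 55.0, 52.2, 54.3 and 54.7%. No intermediate progenitor-like or ependymal-like class could be named, since the panel held only 2 markers of each and a name needed 3. Astrocyte-like, striatal projection neuron-like and subcortical glutamatergic neuron-like cells were too few at some age to be fitted.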

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

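The tests of the splits of the sections, of the mix of clusters, of changes beyond each other class and of the run for the walls were chosen only after the results were seen. Those of a run effect shared by classes and of transcripts from neighbours were written before, although the intervals used to read them were added after.

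Of 83 values examined over the 4 E18 sections, 5 had 1 section far from the other 3, where chance gives about 1 in 20. The share of transcripts past the decoding quality was 96.2% in E18 section 2 and 90.7 to 91.1% in the others, a gap of 0.933 of the range. For genes the gap is a share of the range of log CPM. In E18 section 4 Gfap stood at 249 CPM in radial precursor-like cells against 414 to 446 (gap 0.872) and at 40.1 CPM in whole sections against 63.3 to 65.0 (gap 0.945), and Fam107a at 79.0 CPM in radial precursor-like cells against 45.3 to 49.2 (gap 0.852). Ebf3 stood at 462 CPM in whole E18 section 1 against 414 to 415 (gap 0.983).

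Genes changed in radial precursor-like cells in each comparison, with 194 called from E15 to E18 and 201 from E18 to P2, while each age had its own run. A gene-wise difference between runs that all classes share would give the other classes like changes. Of called genes measured in enough classes, 45.8% from E15 to E18 and 44.2% from E18 to P2 had a median change over other classes in the same direction and at least 0.5 times as large, which decides neither way. For the other classes taken in turn this share was 27.4 to 57.8% from E15 to E18 and 41.5 to 74.3% from E18 to P2. From E18 to P2 12.4% of called genes, 25 in all, changed further than in each of the 8 other classes. With all 25 counted, this argues against a shared run effect alone for them as a set. Among the 25 are Acsbg1, Hes1 and Mt3, which lead a cluster, and the share was not taken without them. The 25 were chosen by this same test, so it gives no separate support for single genes. Of the 11 higher ones 9 stood below their neighbours, and astrocyte-like cells were not among the 8 classes. From E15 to E18 3.61% changed further than in each class, which leaves it open. A changed mix of the 2 clusters is argued against as the whole cause, since 77.3% and 80.1% of called genes were called the same way within at least 1 cluster alone and opposite in none. In both clusters 45.4% and 51.2% were called the same way, and in neither 14.4% and 10.9%. Age cannot be told apart from run and the injection from E15 to E18, or from run and strain from E18 to P2. The exception is a run effect shared by classes, which is argued against for the 25 genes as a set, with those that lead a cluster counted.

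The 100 genes higher at P2 than at E18 in radial precursor-like cells may include transcripts of neighbouring cells. Of them 12% stood above the level of the other cells within 30 µm in all 3 P2 sections, a share as low as neighbours as a source would give. The share over all genes tested was not set beside it, so the low share alone does not point to neighbours. For the 12 genes above their neighbours, Egfr, Olig2 and Jag1 among them, neighbours at this level cannot be the whole source. A biological change of the precursors with age stays open and untested for the other genes.

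The age change differed between roof and lateral wall by the interaction test for the genes that follow. From E15 to E18 the difference, roof minus lateral wall, was 3.80 for Olig1, 2.11 for Fign, 2.09 for Sema6a, 2.07 for Gsg1l, 1.89 for Egfr, 1.56 for Olig2 and 0.89 for Dlx2. It was -3.29 for Rmst, -2.49 for Spp1, -2.01 for Chodl, -1.94 for Sema3e and -1.84 for Rprm. From E18 to P2 it was 3.43 for Ndst3, 3.02 for Dlx2, 2.88 for Sp9 and 1.07 for Egfr, and -3.74 for Pou3f1, -3.49 for Fam107a, -1.70 for Plcxd2, -1.69 for Foxp2 and -1.59 for Gadd45a. From E15 to P2 it was 3.91 for Dlx2, 3.85 for Dlx1, 3.85 for Olig1, 2.96 for Egfr, 1.74 for Olig2 and 0.50 for Slc1a3, and -5.16 for Fam107a, -4.57 for Chodl, -4.15 for Pou3f1, -3.73 for Rmst, -3.36 for Trpc4 and -0.93 for Mki67. At P2 Fam107a had 5 roof transcripts, all in P2 section 1, Pou3f1 had 9 at the roof and 5 at the lateral wall, and Chodl had 4 and 8.

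For the 20 genes with a more positive change at the roof from E18 to P2, a run effect shared by all cells is argued against only with all sections in the fit, since both walls lie in the same sections and yet the change of 9.68% of 310 genes differed between them. When single sections were left out the 30 genes ranged from 13 to 41 and the 20 from 9 to 22. They were 15 of 314 without P2 section 1 and 13 of 317 without P2 section 3, both under the 5% set for this test. A fit with fewer P2 sections can detect fewer changes, so a count under that line does not by itself point to a run effect. Transcripts of neighbours could account for part. Of the 20 genes 25% stood above the other cells within 30 µm of the roof cells in all 3 P2 sections, too few genes to decide. The share over all genes was not set beside it, so the 25% points neither toward nor away from neighbours. Dlx2, Dlx1 and Sp9 were below their neighbours there and Egfr above. The subpallial-type cluster went from 0.968% of the roof cells at E18 to 26.1% at P2, while it held 99.3% and 98.4% at the lateral wall. In the pallial-type cells of the roof alone Dlx2 rose by 2.88, Dlx1 by 3.06, Sp9 by 3.33 and Egfr by 2.53 from E18 to P2, and the difference between the walls was not refitted without the subpallial-type cluster. A biological difference between the walls stays open.

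Splits of the same sections into groups of the same sizes were refitted. For each of these counts, 1 of 35 splits, the real one, gave as many genes, which is the smallest share that 35 splits allow. The other splits mix ages and runs within a group, which widens the spread and lowers their counts. The groups thus differed beyond such splits, but chance is not excluded, since sections may share animals and the counts were not adjusted for their number. In whole sections the real count was 219 from E15 to E18 (highest other 92) and 253 from E18 to P2 (175). In radial precursor-like cells it was 194 (29) and 201 (13), at the lateral wall 71 (1) and 98 (2), in the roof strip 120 (45) and 162 (46), for the interaction 41 (7) and 30 (4), and summed over the 8 other classes and cluster 8 1347 (244) and 1769 (821). From E15 to P2 only 10 splits exist, too few for a share under 0.05. There 1 split gave as many, with counts of 271 in whole sections, 212 in radial precursor-like cells, 129 at the lateral wall, 196 in the roof strip, 66 for the interaction and 1923 over classes, each with 0 as the highest other. Between walls, exchanges within sections number 4 at E15 and P2 and 8 at E18, too few as well, with 145, 150 and 63 genes, 1 exchange with as many and 0 as the highest other. For lists at an unadjusted p under 0.05, 30 of 35 splits gave at least the 2 found from E15 to E18 (highest other 9) and 9 of 35 at least the 4 from E18 to P2 (highest other 6), so chance cannot be excluded. From E15 to P2 it was 1 of 10, too few, with 7 found and 6 as the highest other.

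Codewords that stand for no gene of the panel also gave transcripts. The unassigned codeword with the most had a mean of 1422 per E15 section, 2542 per E18 section and 3196 per P2 section, and the deprecated codeword 3039, 4723.5 and 8333. A negative control codeword had a mean of 14.7, 10.4 and 16.9 and a negative control probe 61.6, 173 and 79.5.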

How the results depend on the processing

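The walls, the roof strip, the clusters fitted alone, cluster 8, and the radial precursor-like cells at the roof and the pallial-type ones among them were chosen after seeing the data. Among named genes, 6267 values kept direction and side of the threshold, 43 gained a call, 165 lost one and 40 reversed. Among counts and main results 846 stayed, 77 moved, 8 weakened and 1 strengthened. Counts follow as main to alternative, and single genes, given with the alternative value, are those whose direction turned. The cause was not tested unless given.

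With library totals in place of TMM, Aldoc in whole sections went to 0.16, 0.23 and 0.38 and Slc1a3 from E15 to P2 to 0.26. With TMM Aldoc was -0.0771 from E15 to E18 and -0.2111 from E15 to P2. Lower genes went from 130 to 78 and 138 to 78 in whole sections from E18 to P2 and E15 to P2. In the same order they went from 95 to 46 and 99 to 59 in subpallial progenitor-like, 123 to 72 and 116 to 71 in interneuron-like and 88 to 53 and 88 to 54 in cluster 8 cells. They went from 101 to 57 in pallial neuron-like cells from E15 to E18, and from E18 to P2 from 100 to 54 in oligodendrocyte lineage-like cells. Cajal-Retzius-like cells from E18 to P2 went from 58 to 90 higher and 87 to 43 lower, and microglia-like cells from 80 to 121 higher. Meningeal fibroblast-like cells went from 85 to 49 higher and 71 to 122 lower from E15 to E18, and from 78 to 143 and 80 to 31 from E18 to P2. Between walls at P2 28 higher became 43 and 35 lower 23, and for the interaction from E15 to P2 32 lower became 21. Lists past the threshold went from 0 to 2, and the astrocyte list from E18 to P2 turned direction (adjusted p = 0.970).

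With at least 50% of the 10 nearest cells of the same class, 1 P2 section of 59 cells was left, assumed to vary like the other groups. Fewer sections and fewer cells by construction lower the counts. Cells lying among other classes were left out at the same time, so these effects cannot be told apart. Of 201 genes from E18 to P2, 44 were left (13 higher, 31 lower), with Foxj1 at -0.0875 and Mki67 at 0.0814. From E15 to P2 212 became 80 (30 and 50). A gene with 3 counts or fewer in a group under an alternative has no value there, among them Spp1, Lama1 and Ebf3 with 0 in that P2 section, Fam107a at the roof without P2 section 1 (0) and Inpp4b at the lateral wall without P2 section 1 (3) or 2 (1). Thinned to the smallest section total, 194 from E15 to E18 became 120 (63 and 57), with fewer transcripts by construction.

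In the subpallial-type cluster alone, 194 became 117 (58 and 59), Rmst 1.11 and Dlx2 -0.70 from E15 to E18. Pou3f1 became 0.53, Dlx2 -0.22 and Emx1 0.385 from E18 to P2, and Emx1 0.25 and Dlx2 -0.92 from E15 to P2. In the pallial-type cluster alone Foxj1 became -0.40 from E18 to P2. At resolution 2 Dlx2 became -0.22, -0.23 and -0.44, Foxj1 -0.31 from E18 to P2 and Aldoc -0.53 from E15 to P2. At the roof 201 became 121 (62 and 59) on fewer cells, and Aldoc -0.23 from E15 to P2. In the pallial-type cells of the roof alone, with 2 P2 sections, 105 higher became 69 from E15 to E18, 201 became 101 (45 and 56) from E18 to P2, and 106 higher became 64 and Aldoc -0.71 from E15 to P2.

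In the roof strip Dlx2 from E15 to E18 was -0.0197 with DESeq2. At 30 µm Gsx2 became -0.50 from E15 to E18, from 0.2086 in the main strip, and Olig2 -0.17 from E18 to P2. At 100 µm Aldoc became -0.0938 from E15 to P2. With all cells at the walls, 63 genes at P2 became 124 (60 and 64), and the interaction went from 30 to 82 (48 and 34) from E18 to P2 and from 66 to 121 (72 and 49) from E15 to P2. Unthinned, the proliferation difference was -4.22 points (exact p = 0.0571) from E15 to E18 and -5.82 (exact p = 0.0286) from E18 to P2.

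Leaving out each section gave these ranges, with the sections behind them. Whole sections had Aldoc at -0.32 to 0.37 from E15 to E18 and -0.44 to 0.23 from E15 to P2 (E15 section 2) and Foxj1 from E15 to P2 at -0.0144 to 0.25 (P2 section 3). Dlx2 from E15 to E18 was -0.21 to 0.29 in radial precursor-like cells (E15 section 2) and -0.27 to 0.44 in the roof strip (E15 2 and 3, E18 1), where Gsx2 was -0.77 to 0.64 (E15 3, E18 1). At the lateral wall 71 was 47 to 94 and 40 higher 23 to 48 (E15 1), and 45 higher from E18 to P2 25 to 52 (P2 1 and 2). Between walls at P2 63 was 39 to 69 (P2 2), 28 higher 20 to 43 (E15 2) and 35 lower 12 to 34 (E18 2, P2 2), and at E18 81 lower was 53 to 80 (E18 2). For the interaction, 41 was 27 to 59 (E18 3) and 16 lower 10 to 32 (E15 2 and 3, E18 2 and 3, P2 3) from E15 to E18. For E18 to P2 30 was 13 to 41 and 20 higher 9 to 22 (each P2 section), and 10 lower 3 to 19 (E15 2, E18 4, each P2 section). From E15 to P2 32 lower was 19 to 36 (P2 1). Adjusted p of lists that turned direction was 0.596 to 0.969 for endothelial (E15 1), 0.762 to 0.919 for interneuron (E15 2) and 0.902 to 0.996 for striatal genes (E18 3) from E15 to E18, and 0.817 to 0.969 for astrocyte (P2 1) and 0.422 to 0.962 for endothelial genes (P2 2) from E18 to P2. The proliferation difference from E15 to E18 was -16.6 to -13.3, with too few sections left to reach 0.05.

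Replicate numbers were not taken to pair the sections, since not every same-numbered pair correlated over 0.1. In whole sections the deviations of same-numbered sections correlated at -0.0414 to 0.294, 6 of 9 pairs over 0.1, beside a median of -0.0521 for other pairs, and 6 of 10 sections correlated best with their own number. In radial precursor-like cells it was -0.0491 to 0.179, 3 of 9 pairs, a median of -0.0196 and 5 of 10 sections. With the number as a block 205, 238 and 272 genes were called in whole sections and 176, 195 and 213 in radial precursor-like cells. DESeq2 called 225, 260 and 276, and 199, 205 and 222. The stricter votes for dorsal and ventral cells, and the alternatives for shares of cells and neighbours, were not run, because the vote and those comparisons could not be made.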

Other observations

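The test of changes beyond each other class and that of the mix of clusters were chosen only after the result was seen.

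Cluster 8, unnamed and led by Eomes, Nrn1, Slc17a6 and Neurod1, was fitted alone after seeing the data. From E15 to E18 Egfr rose there by 4.21 ± 0.22 (SE, edgeR quasi-likelihood, adjusted p = 9.9e-10) and Olig1 by 3.06 ± 0.31, while the glutamate transporter gene Slc17a7 changed by -2.57 ± 0.18 and Cdh6 by -1.88 ± 0.13. Between E18 and P2 Gfap rose by 6.44 ± 0.17, Gpr17 by 4.30 ± 0.31 and Prex2 by 3.95 ± 0.21, and Ebf3 changed by -3.58 ± 0.35. Of 318 genes, 84 rose and 72 fell, 100 rose and 88 fell, and 112 rose and 88 fell in the 3 comparisons. Without TMM the share higher moved from 53.9 to 66.9%, 53.2 to 70.2% and 56.0 to 73.7%.

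Egfr rose from E15 to E18 in other classes too. It rose by 2.52 ± 0.23 in subpallial progenitor-like, 2.52 ± 0.32 in oligodendrocyte lineage-like and 2.31 ± 0.32 in interneuron-like cells, and its median over the 8 other classes was 1.96 (range -0.17 to 2.52). From E18 to P2 that median was 0.57 (range 0.07 to 1.81), beside 1.46 in radial precursor-like cells.

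Inpp4b and Cdh6 changed further from E18 to P2 in radial precursor-like cells than in each of the 8 other classes, by -3.17 and -1.97 beyond the nearest class. A candidate explanation is a loss of their expression in the precursors, since their median change over the other classes was -0.075 and 0.06, although in cluster 8 they changed by -0.82 and -0.81. Whether such a loss is particular to the precursors cannot be told, since astrocyte-like cells and cluster 24 were not among the 8 classes. Inpp4b is also among the 20 leading genes of the subpallial-type cluster. The share of called genes with such a change was 12.4%. Inpp4b and Cdh6 were chosen from those genes, so this share gives no separate support for either of them. Both also fell within each cluster alone, Inpp4b by 3.33 and 3.87 and Cdh6 by 1.91 and 2.59 in the pallial-type and subpallial-type cluster. Run and strain effects that act on these cells alone were not tested.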
